A study of Danio rerio with 7 samples.

How the data were processed

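RNA from zebrafish tail fin was sequenced in 7 libraries. One was a control library, whose labels give neither an edge nor a time after amputation. The other 6 came from cut fins, from an edge of the cut, anterior (ACE) or posterior (PCE), collected 24, 48 or 72 h post amputation. Each group held 1 library, and the labels do not say how many fish were pooled in it. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an NEBNext Ultra kit for Illumina sequencing.

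The deposited table held FPKM values (fragments per kilobase of feature, scaled to the library's fragments) that the authors computed, with 1 column per library. Per the submitters' processing notes, HISAT2 2.0.5, HTSeq 0.9.1 and edgeR were used, with no role or order stated. The genome build, the annotation and the way the features were made are not given in the sources used here. The table listed 433380 features, and all of their identifiers had the form "Cluster", a number, a point and a second number. None of them (0) was found among the identifiers and names of the zebrafish reference tables, and the table does not pair them with gene names. They are called clusters here. A first number groups clusters, and 253955 of them (58.6%) shared a single first number, while the next most used one had 24 members. What a first number stands for is not given in the sources used here. Near-identical transcripts could be split between clusters, so the level of a single cluster is uncertain in that respect.

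Because no cluster carried a gene name, the 25 gene lists and the naming rule for 12 genes per direction, all written before the data were examined, could not be applied. The ranking of that rule was kept and applied to cluster identifiers. Among clusters with the same sign in every pair of libraries compared, the 2 highest and the 2 lowest by the smallest size of the difference over the pairs were named in each of the 3 fitted comparisons. One further cluster, the one with the highest value in the table, was singled out after its values were seen. The planned naming of clusters at single times was left out, since identifiers alone carry no biology. The designs of the tests and most alternatives were likewise chosen before the data were examined.

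Values were analysed as log2(FPKM + 1), a scale that understates differences of low clusters. Clusters with a mean FPKM over the 7 libraries of at least 1 were kept, which left 122784. Limma 3.58.1 in R 4.3.3 was used with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. The edge comparison was PCE minus ACE over the 6 libraries of cut fins with time as a factor, and the time comparison was 72 minus 24 h in the same fit. Both had 2 residual degrees of freedom, so their error was the change of the edge difference between times plus library noise. The comparison of cut fins with the control used all 7 libraries, and the lone control was assumed to vary like the cut libraries. P-values measure only the spread between these libraries. At a single time there was 1 library per edge, so these differences have no replicate check, and clusters were counted by a fixed rule, a difference of at least 1 on the log2 scale. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for counts, correlations and plots.

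The limma step was tested on simulated data with 200 changed clusters. Over 122784 clusters, 0% of clusters changed by 6 on the log2 scale were recovered in each of the 3 comparisons, although the median estimate lay close to the simulated change (5.98 for the edge). Over the 37170 clusters with a mean FPKM of at least 5, 38.5% of clusters changed by 6 were recovered for the edge, and 0% for the other comparisons. Over 122784 clusters a count of 0 calls therefore does not exclude 200 clusters changed by as much. Larger numbers of changed clusters, for which recovery after adjustment can be higher, were not simulated. The simulated values were normal around each cluster's mean, without the many values of 0 in the real data. How many differing clusters a count of 0 calls could hide is therefore not known.

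The number of reads per library is not stated in the table. Low values step by what 1 read is worth, so relative depth was estimated from the log2 ratios of pairs of libraries over clusters with low values (0.15 to 0.3 FPKM) that were above 0 in at most 4 libraries. On simulated data the largest error was 0.0019 on the log2 scale when all libraries shared effective lengths, and 0.21 when effective lengths differed by 100 bases. Whole reads could not be recovered per cluster, because the cluster lengths were not used here.

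The other settings chosen beforehand were a pseudocount of 0.1, a minimum mean FPKM of 5, no such minimum, median-of-ratios scaling, quantile normalization, limma without the trend, an adjusted p threshold of 0.1, other codings of time, a size threshold of 1.5-fold, and leaving out a library or a pair of libraries in turn. Settings chosen after seeing the data were clusters above 0 in at least 4 libraries, fits and counts without the PCE 24 h library or the 24 h pair, and a detection limit of 1 FPKM.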

Results

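Gene expression during regeneration of the amputated zebrafish tail fin was measured by RNA sequencing in 7 libraries, namely 1 control and, at 24, 48 and 72 h post amputation, 1 library from each side of the cut, the anterior edge (ACE) or the posterior edge (PCE). The title of the study concerns calcineurin, a calcium-dependent phosphatase, and the polarity of the blastema, the proliferating tissue from which the fin regrows. The features carry cluster identifiers without gene names, so levels are given for clusters and not for genes. The libraries had no replicates, and errors below come from fits over several libraries.

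Relative to a depth of 1 for the control, estimated depth was 1.14, 0.899 and 1.13 in ACE at 24, 48 and 72 h, and 0.745, 0.988 and 0.771 in PCE. The control held 170017 clusters above 0. The ACE libraries held 122838, 143247 and 181371 at 24, 48 and 72 h, and the PCE libraries held 122580, 115844 and 96680. In all, 27986 clusters were above 0 in every library, 117367 in 1 library only, and 94535 were listed at 0 in every library. Total FPKM ranged from 1748110 in ACE 72 h to 3010860 in PCE 24 h.

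The PCE 24 h library stood apart in its makeup. Clusters above 0 in that library alone numbered 33560 and held 29.3% of its total FPKM, against 1.96% to 7.45% in the other libraries. Their median was 10.8 FPKM. The clusters shared by all 7 libraries held 53.2% of its total, against 79.2% to 82.2% elsewhere. Several counts that include this library are therefore also given without it.

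**Figure D1:**
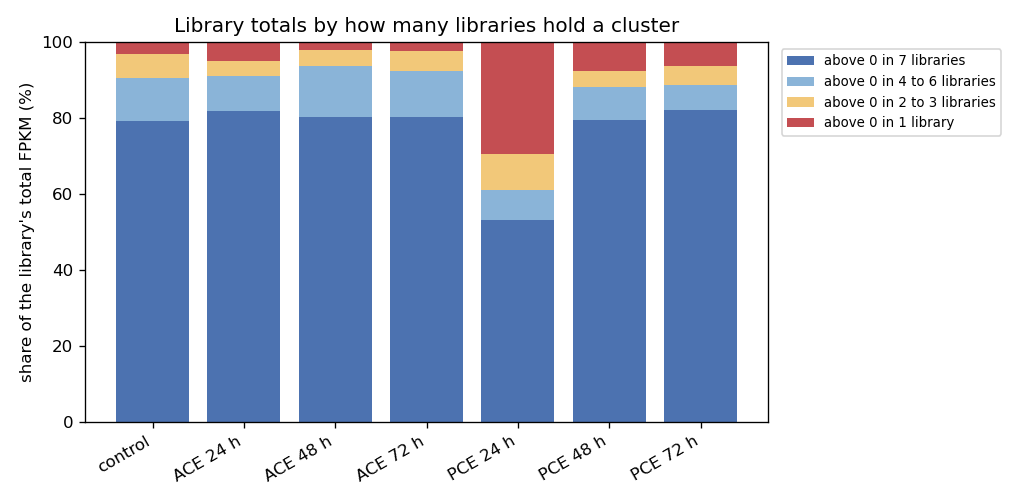
Stacked bars show the share of each library's total FPKM (percent, y axis) held by clusters above 0 in 1, 2 to 3, 4 to 6 or all 7 libraries. In PCE 24 h the clusters of that library alone held 29.3%, against at most 7.45% in the other 6 libraries.

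Over the 27986 clusters shared by all libraries, the 6 libraries of cut fins were mostly closer to each other than to the control. Pearson's r of log2(FPKM + 1) across clusters was 0.775 to 0.924 between cut libraries and 0.669 to 0.799 between a cut library and the control. Among cut libraries ACE 72 h was the nearest to the control (r = 0.799), and it was nearer to the control than to PCE 24 h (r = 0.775). PCE 72 h was the farthest from the control (r = 0.669). The highest r was between ACE 48 h and PCE 48 h (0.924). Over the 122784 clusters with a mean FPKM of at least 1, r between PCE 24 h and the other libraries was only 0.031 to 0.120. In that set the highest r was between ACE 48 h and ACE 72 h (0.749), against 0.589 between the edges at 48 h. PCE 24 h was then the farthest from the control (0.052). Clusters are not independent replicates, so no p-value is given.

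**Figure D2:**
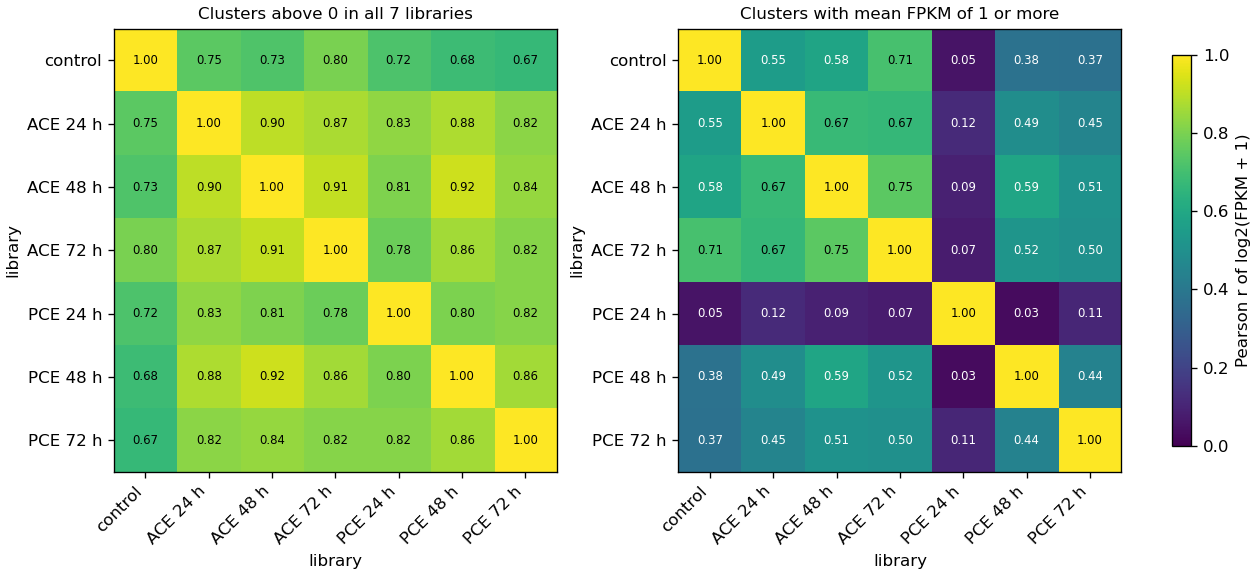
Heat maps of Pearson's r of log2(FPKM + 1) across clusters for each pair of the 7 libraries, over the 27986 clusters above 0 in all of them (left) and the 122784 with a mean FPKM of at least 1 (right). On the left r is 0.775 or more between cut libraries and at most 0.799 with the control, and on the right PCE 24 h lies apart from all others (at most 0.120).

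The first comparison asked which clusters differed between the posterior and the anterior edge at all 3 times. Cluster-86133.0 was listed at 0 in the control and in every ACE library, and stood at 66.1, 79.1 and 119.5 FPKM in PCE at 24, 48 and 72 h. Cluster-118330.201012 was also listed at 0 in every ACE library, with 8.36 FPKM in the control and 2774, 183 and 110.2 FPKM in the PCE libraries. In the other direction, Cluster-118330.110302 stood at 59.4 FPKM in the control and at 73.9, 81.1 and 131 FPKM in ACE, and Cluster-118330.88017 at 61.3 FPKM in the control and at 54.0, 59.2 and 49.6 FPKM in ACE. Both were listed at 0 in all 3 PCE libraries. By limma with Benjamini-Hochberg adjustment, each of these 4 clusters had an adjusted p of 0.475. Having the same direction in 3 of 3 pairs was a condition of their naming and adds no support.

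More widely, 1341 clusters were higher and 3133 lower in PCE by at least 1 on the log2 scale at every time, while 3815 differed by as much at every time in mixed directions. With median-of-ratios scaling the counts were 1655 higher and 2145 lower, and with quantile normalization 1126 higher and 4975 lower. Without the 24 h pair, 4609 were higher and 9035 lower at both remaining times, and 5047 went in opposite directions. Among clusters with a mean FPKM of at least 1, those above 0 in all 3 ACE libraries and in no PCE library numbered 2141, the most of the 20 possible sets of 3 cut libraries, and those above 0 in all 3 PCE libraries and no ACE library numbered 1448, the next most, ahead of a mixed set with 1351. Over all clusters the ACE set had 8977, again the most, but the PCE set had 2017 and ranked 7 of 20, and the highest mixed set had 5222. Without PCE 24 h and with a mean of at least 1, 3628 clusters were above 0 in the 3 ACE libraries and no other cut library. In PCE 48 h and PCE 72 h and no other cut library there were 2977, and in ACE 48 h and ACE 72 h 2909. Over all clusters these pairs had 5300, rank 4 of 10, and 17310. None of these ranks takes account of how many clusters each library held above 0. That number was 122838, 143247 and 181371 in ACE at 24, 48 and 72 h, and 122580, 115844 and 96680 in PCE. The lead of the ACE set is therefore by itself no measure of an edge difference.

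Limma called 0 clusters for the edge, with 4396 at an unadjusted p under 0.05 of 122784 tested, and also called 0 without PCE 24 h, with 6514 at an unadjusted p under 0.05. If p-values were spread evenly with no change at all, 5% of the tested clusters, or 6139, would fall under that level in each comparison. That spread was not checked. Many clusters were high in 1 library alone, with PCE 24 h above every other library by at least 1 in 32691. The p-values of such clusters need not be spread evenly. The counts at an unadjusted p under 0.05, here and in the 2 comparisons below, are therefore not read against 6139. The PCE minus ACE differences of the 3 times were weakly related across clusters, with Pearson's r of 0.0550 (24 and 48 h), 0.166 (24 and 72 h) and 0.168 (48 and 72 h).

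**Figure D3:**
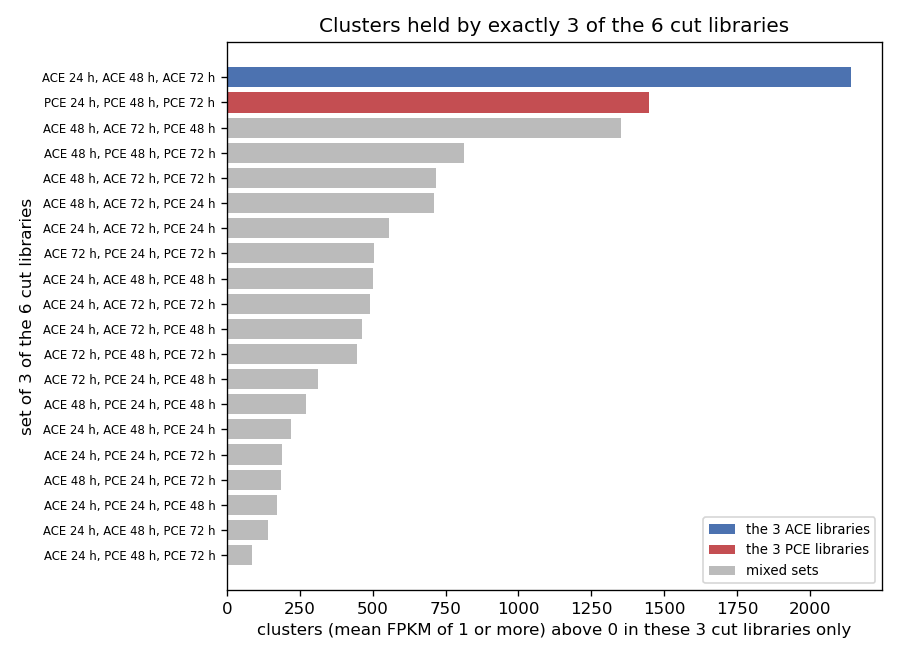
Bars give the number of clusters (x axis, mean FPKM of at least 1) above 0 in exactly the 3 cut libraries named on the y axis, for all 20 sets of 3. The set of ACE libraries (2141) and the set of PCE libraries (1448) are the highest bars, followed by a mixed set with 1351. The bars take no account of how many clusters each library held above 0.

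At single times, PCE and ACE differed by at least 1 on the log2 scale in 67260 clusters at 24 h (54.8% of those tested), in 39050 at 48 h (31.8%) and in 50912 at 72 h (41.5%). The share of these that was higher in PCE was 63.6% at 24 h, 50.5% at 48 h and 37.0% at 72 h. Quantile normalization gave 44.4%, 46.4% and 45.3%, and median-of-ratios scaling gave 66.4%, 55.4% and 48.9%. That scaling raised PCE minus ACE by 0.24, 0.22 and 0.70 on the log2 scale at 24, 48 and 72 h. Among clusters above 0 in at least 4 libraries, a restriction chosen after seeing the data, the shares were 37.3%, 34.7% and 24.3%. Of the 42797 clusters higher in PCE at 24 h, 32691 had PCE 24 h above every other library by at least 1. The next highest number for a library was 8281 (PCE 48 h). Such clusters can pass the minimum mean through 1 library alone. The count and the share at 24 h therefore largely describe the PCE 24 h library.

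Cluster-118330.128325 had the highest value in the table and was singled out for that reason. It stood at 259640 FPKM in PCE 48 h and 280779 FPKM in PCE 72 h, which was 10.1% of the total of the former and 12.99% of that of the latter. The control had 11561 FPKM, the ACE libraries 32500, 44130 and 13912 FPKM at 24, 48 and 72 h, and PCE 24 h 17957 FPKM.

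The second comparison asked what differed between 72 and 24 h at both edges. Cluster-118330.206391 was at 485 FPKM in ACE 72 h and 3805 FPKM in PCE 72 h, and was listed at 0 in the other 5 libraries. Cluster-118330.222654 was at 195 and 754 FPKM in these 2 libraries, at 0.55 FPKM in the control and listed at 0 in the rest. Cluster-85539.2 and Cluster-85539.1, which share a first number, were seen only at 24 h. Cluster-85539.2 stood at 1407 FPKM in ACE and 5010.4 FPKM in PCE, and Cluster-85539.1 at 1386 and 4739.5 FPKM. Limma's adjusted p was 0.466 for the first pair of clusters and 0.403 for the second. Having the same direction at 2 of 2 edges was a condition of their naming. With a mean FPKM of at least 5, limma's adjusted p was 0.0387 for Cluster-118330.206391 and 0.0367 for both Cluster-85539.2 and Cluster-85539.1, calls that are lost without PCE 24 h, where 1 residual degree of freedom remains. With a mean of at least 1, leaving out PCE 24 h moved the fitted differences of these clusters by less than 1 on the log2 scale. They were named for a large difference at each edge, so this does not decide whether the calls rest on that library. Without PCE 24 h, ACE 24 h is fitted exactly, and the residual spread of Cluster-85539.2 and Cluster-85539.1 is 0. Their adjusted p in that fit therefore measures no spread of their own. Over the settings run, the adjusted p of limma for the 3 clusters called at a mean of at least 5 ran from 0.0367 to 0.609.

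From 24 to 72 h, 4586 clusters were higher and 4287 lower by at least 1 at both edges, while 6056 went in opposite directions. Quantile normalization gave 7369 higher and 2694 lower. From 48 to 72 h, which leaves out the PCE 24 h library, 3333 were higher and 5101 lower at both edges, and 5153 went in opposite directions. Limma called 0 clusters for 72 against 24 h, with 3581 at an unadjusted p under 0.05, but 19 (11 higher, 8 lower) with a mean FPKM of at least 5, and 0 at that minimum without PCE 24 h. Without ACE 24 h the call count was 25589, a value that rests on PCE 24 h as the only library of that time. The change from 24 to 72 h in ACE was weakly related across clusters to that in PCE (r = 0.0709), as were those from 24 to 48 h (r = 0.0992) and from 48 to 72 h (r = 0.0890). Among clusters above 0 in at least 4 libraries these values were 0.130, 0.191 and 0.188.

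The third comparison set the 6 libraries of cut fins against the control. Cluster-118330.122426 was listed at 0 in the control and stood at 2267, 769 and 336 FPKM in ACE at 24, 48 and 72 h, and at 2454, 748 and 628 FPKM in PCE. Cluster-118330.134697 was at 0.57 FPKM in the control, 534, 428 and 426 FPKM in ACE and 303, 828 and 278 FPKM in PCE. Its difference was 8.12 ± 0.63 (SE) on the log2 scale, with a limma adjusted p of 0.496. Having the same direction in 6 of 6 libraries was a condition of its naming. Cluster-137491.0 and Cluster-118330.128806 were at 296 and 188 FPKM in the control and listed at 0 in all 6 cut libraries. The control is fitted exactly, so on the deposited values the residual spread of these clusters is 0. Their adjusted p therefore measures no spread of their own between libraries. With a mean FPKM of at least 5, limma's adjusted p was 0.0030 for Cluster-118330.122426 and 0.0052 for Cluster-118330.134697, but at that minimum without PCE 24 h neither was called. Leaving out that library also lowers the residual degrees of freedom from 2 to 1. With a mean of at least 1 the differences were then no smaller than with it. They were 9.93 (9.87 with it) for Cluster-118330.122426 and 8.28 for Cluster-118330.134697. Both were named for a large difference in every cut library, so this does not decide whether the calls rest on PCE 24 h. Over the settings run for these clusters limma's adjusted p ran from 0.0030 to 0.523 for the former and from 0.0052 to 0.523 for the latter, with 0.166 and 0.291 without PCE 24 h at a mean of at least 1. For Cluster-137491.0 and Cluster-118330.128806 limma's adjusted p was 0.496 each, 0.0052 each with no minimum, and 0.158 and 0.220 with a mean of at least 5, in a range of 0.0052 to 0.523 over the settings run.

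In all 6 cut libraries, 2430 clusters were higher and 6997 lower than the control by at least 1, and with no minimum mean 2430 higher and 20722 lower. With a mean FPKM of at least 5 the counts were 1987 higher and 1554 lower, but that mean is taken over 6 cut libraries and 1 control, so the minimum itself keeps clusters high in cut fins and removes those high only in the control. Quantile normalization gave 1378 higher and 8477 lower. These counts share 1 control library. By any amount, 6.40% of clusters were higher and 14.6% lower in every cut library than in the control. The 7 libraries were on average the lowest of all in 4.48% of clusters and the highest in 14.3%, and among cut libraries PCE 24 h (7.44%) and PCE 72 h (8.73%) were the lowest more often than the control. PCE 24 h was the highest in 33.5% of clusters and raised that mean, while the other cut libraries were the highest in 8.86% to 13.6%. Under the rule of at least 1, among the cut libraries, the number of clusters in which a library lay below all others by at least 1 ran from 113 (ACE 72 h) to 2576 (PCE 24 h), and above all others from 2648 (ACE 72 h) to 32691 (PCE 24 h). Without PCE 24 h, 3776 clusters were higher and 8372 lower than the control. Clusters above 0 in all 6 cut libraries and listed at 0 in the control numbered 2241, and clusters seen in the control alone numbered 24029. Of these, 769 and 87 had a mean FPKM of at least 5, a minimum that favours the former in the same way.

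Limma called 0 clusters for cut fins against the control, with 9444 at an unadjusted p under 0.05. With a mean FPKM of at least 5 it called 270 (241 higher and 29 lower in cut fins), but without PCE 24 h at that minimum 132, all of them lower, and with no minimum it called 27498 (302 higher, 27196 lower). The control is fitted exactly, so a cluster seen in it alone has no residual spread, and a lower call for it measures none. With no minimum, 24029 such clusters entered the fit. Without ACE 24 h or without PCE 24 h, the remaining 24 h library is fitted exactly as well. A cluster seen in that library alone then has no residual spread either, and PCE 24 h held 33560 such clusters. Calls from those fits are therefore not read as changes.

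Low values showed a grouping of libraries that the labels do not give, and its origin was not tested. The steps of low values at 1.2 to 2.5 FPKM matched best in 6 of 21 pairs of libraries, with a peak height of 3.38 SD or more. These pairs form 2 sets of 3 libraries, the control with ACE 24 h and PCE 72 h, and ACE 48 h with ACE 72 h and PCE 48 h. PCE 24 h was in neither. The next pair, PCE 48 h with PCE 72 h, had a peak height of 2.87 and would join the sets, so they depend on where the bound is placed. Only the edges at 48 h lay within 1 set, and their difference, 39050 clusters, was the smallest of the 3 times. Within the set of the control, 43879 clusters differed by at least 1 between ACE 24 h and the control and 54843 between PCE 72 h and the control, against 35930 to 73611 for the cut libraries outside it. No set held both 24 and 72 h of 1 edge, so the change from 24 to 72 h has no value within a set.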

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

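In this part, the restriction to clusters above 0 in at least 4 libraries and the test of library preparation for the cluster with the highest value were chosen after the result was seen, while the test of scaling was set before. No group had 4 or more libraries, so none was examined for a library far from the others.

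The share of clusters differing by at least 1 that was higher in PCE lay above 50% at 24 h (63.6%) and 48 h (50.5%) and below it at 72 h (37.0%). This opposite balance drew attention, but it depends on the processing. Median-of-ratios scaling kept it (66.4%, 55.4% and 48.9%), as did a mean FPKM of at least 5 (60.7%, 50.2% and 34.6%). Quantile normalization gave 44.4%, 46.4% and 45.3%, clusters above 0 in at least 4 libraries gave 37.3%, 34.7% and 24.3%, and the share at 48 h was 48.5% with a pseudocount of 0.1. At 24 h, 32691 of the 42797 clusters higher in PCE had PCE 24 h above every other library by at least 1. The difference between times was not tested, since each time had 1 library per edge.

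Cluster-118330.128325 also differed between times. PCE minus ACE was −0.86 at 24 h, 2.56 at 48 h and 4.33 at 72 h on the log2 scale, and the difference between times was not tested. The tables argue against library scaling as the cause, since the smaller of the differences at 48 and 72 h was 2.77 after median-of-ratios scaling. Matching read steps cannot decide on a library preparation as the cause. At 1.2 to 2.5 FPKM, PCE 48 h matched ACE 48 h and ACE 72 h better than PCE 72 h. There PCE 72 h matched the control and ACE 24 h better than PCE 48 h. The lower of the pair was 5.88 times the highest of these other libraries. At 0.15 to 0.3 FPKM, however, PCE 48 h and PCE 72 h matched each other better, with a peak height of 3.96 against at most 3.69 for those pairs. Whether the steps reflect preparation was not tested. Reads shared with near-identical clusters were not tested and stay open, as does a change at the posterior edge after 24 h, which may be followed up as a hypothesis.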

How the results depend on the processing

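Settings named here as added were chosen after the results were seen, namely clusters above 0 in at least 4 libraries, leaving out PCE 24 h beyond the planned leave-one-out fits, and differences without the 24 h pair or from 48 h on. Libraries were paired by time in the edge fit itself, and pairing by replicate number was not run because the labels give none. The gene lists were not run, since no cluster carried a name. The edge count stayed at 0 under every setting except leaving out a pair of libraries in turn (0 to 2, with 2 without the 48 h pair). For 72 against 24 h it was 19 with a mean FPKM of at least 5 and 0 to 25589 with a library left out. For cut fins against the control it was 270 with a mean FPKM of at least 5, 27498 with no minimum (302 higher, 27196 lower), 24 among clusters above 0 in at least 4 libraries (added), 132 without PCE 24 h at a mean of at least 5 (added), and 0 to 26560 with a library left out. All other settings gave 0 calls. Without ACE 24 h, PCE 24 h is the only library of its time and is fitted exactly, which limits the highest counts with a library left out. With no minimum, clusters seen in the control alone have no residual spread, which limits the lower calls there.

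Filters changed the number of clusters counted. At 24, 48 and 72 h, PCE and ACE differed by at least 1 in 20938, 10228 and 15859 clusters with a mean FPKM of at least 5, in 110898, 68471 and 86024 with no minimum, and in 28795, 19477 and 30879 above 0 in at least 4 libraries (added). The share of tested clusters moved as well. It was 49.1%, 33.2% and 52.6% at 24, 48 and 72 h in the added set, and 32.7%, 20.2% and 25.4% with no minimum. The number entering therefore does not account for all of it. Counts in the same direction at all 3 times were 8097 with a pseudocount of 0.1, 1534 with a mean of at least 5 and 13644 without the 24 h pair (added). At both edges from 24 to 72 h they were 13777 and 3393 under the first 2 of these settings. In all 6 cut libraries against the control they were 3541 with a mean of at least 5, 23152 with no minimum and 6059 above 0 in at least 4 libraries (added). Correlations of edge differences moved by 0.05 or more in 3 cases, to 0.125 (24 and 48 h, quantile normalization), 0.105 (24 and 72 h, median-of-ratios scaling) and 0.226 (48 and 72 h, clusters above 0 in at least 4 libraries, added). Over that added set, changes in ACE against PCE correlated at 0.191 (24 to 48 h), 0.130 (24 to 72 h) and 0.188 (48 to 72 h). The cause was not tested where a filter or pseudocount does not itself set the number. Of 89 values of the 12 named clusters under other settings, 78 stayed on the same side of the limma threshold with the same direction, 11 came under it and 0 turned, with adjusted p from 0.0030 to 0.683. These clusters were named for a large difference of the same sign in every pair, so the lack of a turn adds no support. Depth is known only as a ratio between libraries, so no detection floor is given.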

Other observations

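In this part, the tests of depth, of stray single reads and of an outside source for PCE 24 h, its detection limit of 1 FPKM, and the tests of depth and shared preparation for ACE 72 h, were chosen after the results were seen, and the others before.

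Clusters seen in exactly 2 libraries paired most often, relative to independent detection, between PCE libraries, with 2.58 times the expected number for PCE 24 h and PCE 72 h, 2.46 times for PCE 48 h and PCE 72 h, and 1.94 times for PCE 24 h and PCE 48 h. Next came ACE 24 h with PCE 24 h, a pair across edges, at 1.65 times, and the control with ACE 72 h, which shared 18864 such clusters, at 1.64 times. ACE 48 h with PCE 48 h, also across edges, followed at 1.44 times. Of the pairs of ACE libraries, ACE 24 h with ACE 48 h lay above the expected number (1.22 times). ACE 48 h with ACE 72 h (0.964) and ACE 24 h with ACE 72 h (0.889) lay below it. In plain counts these ACE pairs held 5626 and 4045 clusters, and ACE 24 h with ACE 48 h 2565. The PCE pairs held 4004, 2813 and 3576 in the order given above. Expected numbers were fitted to each library's total of such clusters. For the control and ACE 72 h that total includes the 18864 they share, which lowers the ratios of their other pairs. The ratios are therefore by themselves no measure of sharing within an edge. Of the 177 clusters with a mean FPKM of at least 1000, 16 were higher and 24 lower in PCE by at least 1 at 24 h, 11 and 4 at 48 h, and 23 and 57 at 72 h. Median-of-ratios scaling, tried after these counts were seen, turned the balance at 24 h (29 higher and 17 lower) and at 72 h (37 and 14), and gave 13 and 3 at 48 h.

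PCE 24 h held 29.3% of its total FPKM in clusters of no other library, or 31.9% with detection at 1 FPKM. Deeper sequencing is argued against by its relative depth of 0.745, the lowest estimate of the 7. The median of these clusters was 1.46 times the highest such median of another library, which met the bound of 2 set beforehand for stray reads, but PCE 48 h (7.39 FPKM) and PCE 72 h (7.0 FPKM) were themselves far above the control (0.89 FPKM), so that test cannot decide, and against the control scaled to the value of 1 read the median was 9.04 times as high. A pair of explanations stays open, RNA from a source outside the fin mixed into this library, for which r over the shared clusters (lowest 0.775) decides nothing since every pair of cut libraries met the bound and the lowest values all involved PCE 24 h, and transcripts assembled apart from the largest identifier group, outside which 81.7% of these clusters lay, against at most 73.7% in another library. They can both hold, no sequence was used here to tell a source, and a biological difference of the posterior edge at 24 h was not tested.

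ACE 72 h lay nearest to the control (r = 0.799). ACE 24 h, of about the same depth and in the set of the control by read steps, reached only 0.749. This is 1 library, and the origin of the sets was not tested, so neither depth nor a shared preparation can be excluded. ACE 72 h stayed the nearest to the control over clusters with a mean FPKM of at least 5, where its lead over the next library was 0.105. That mean is taken over all 7 libraries, so clusters low in both ACE 72 h and the control can remain. The lead there therefore cannot exclude low clusters seen in both libraries as a part of the nearness. Over the clusters above 0 in all 7 libraries, r with the control was 0.749, 0.726 and 0.799 in ACE at 24, 48 and 72 h. In PCE it was 0.721, 0.684 and 0.669. In that set r fell at each step in PCE and had no steady course in ACE. Over clusters with a mean FPKM of at least 1 or at least 5, r instead rose at each step in ACE. In PCE it then rose from 24 to 48 h and fell slightly to 72 h. The course over time therefore depends on the clusters used. A biological difference between edges or times was not tested, with 1 library per group.

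Other splits of the 6 cut libraries were too few for a share under 0.05. The real split gave 0 limma calls, so all 10 splits into 3 and 3 necessarily reached it and the count decides nothing, and the highest other gave 29920. The 6 splits that keep 2 same-time pairs together gave 7044 to 29920 calls, but they are not fits of the same form. They estimate the difference from 1 parted pair, which is fitted exactly. A cluster seen in 1 library of that pair alone then has no residual spread. Calls numbered 29920 with the 24 h pair parted, 7936 with the 48 h pair and 7044 with the 72 h pair. How many of them are such clusters was not counted. Among the 4 splits that part every same-time pair, the real one had 4396 clusters at an unadjusted p under 0.05 and the highest other 1210, with 1 split as high as the real one, itself. For clusters differing by at least 1 in the same direction at all 3 times, the real assignment gave 4474 and the highest of the other assignments 1631, again 1 of 4.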
